A study of Arabidopsis thaliana with 3 samples.

How the data were processed

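HDA6-GFP ChIP-seq was performed on 14-day-old Arabidopsis seedlings with an antibody against GFP. Per the labels, 2 biological replicates of the ChIP and 1 input were sequenced on an Illumina HiSeq instrument after DNA of at least 5 immunoprecipitations had been pooled for each library. The label of the input also lists the antibody, and it was treated here as input after its title. Bowtie and SICER are named in the submitters' processing notes, with the TAIR10 build. Their versions, roles and settings, the filters and the pooling of replicates are not given in the sources used here.

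The authors deposited both lists as positions in bp, each line giving a sequence name, a start and an end, with no score, count or p-value. Starts are printed here counted from 1. Both lists are taken as pooled over their group, since they carry no replicate number, and no sample could be set against its replicate. SICER joins windows of a fixed size, but region widths that are multiples of 200 bp made up only 0.384% of the ChIP list, so the step that set the final borders is not known. Read depth is unknown, and the precision of a share is set by the number of regions. Wilson intervals at 95% cover counting error only and treat regions as independent, which they are not. How SICER or a mapping filter treated reads with several matches in the genome would decide how many regions appear in repeats, at ribosomal RNA genes and in nuclear copies of organelle DNA, and is also not known.

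Genes were taken from the RefSeq gene table of assembly TAIR10.1, which was used for names and for which genes a region touches. Its nuclear chromosomes were taken as those of TAIR10: the last covered bases of the lists and the last gene bases differ by at most a few kb on each chromosome, all 4 nuclear ribosomal RNA genes overlap a region, and all 220 genes of the fixed lists were found in it. No gene coordinates of the table are printed, and organelle genes were not matched. The table gives no strand and no transposon class. The design fixed before the data were examined had used promoters upstream of genes, distances to transcription starts and transposable elements. In their place stand the 1-kb flanks on both sides of a gene, the distance to either gene end, and the genes annotated as pseudogenes or transcribed pseudogenes. RefSeq commonly places Arabidopsis transposon genes in that class, but the table does not say which of its members are transposons. Motif searches and base composition, which need a genome sequence, were not run. As the lists hold no value per region, the widest regions were used where the design called for those with the highest value.

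Each region midpoint was assigned to 1 class in the order protein-coding gene body, flank, annotated pseudogene, other. Shares were compared with 1000 random placements that kept chromosome and width, by a two-sided permutation test with Benjamini-Hochberg adjustment over the 4 classes. Pericentromeres were set as 3 Mb on either side of centromere midpoints at 15, 3.6, 14, 4 and 11.7 Mb on chromosomes 1 to 5. For 23 gene lists (10 of named genes and 13 families defined by symbol), the number of genes with a region overlapping the body or 1-kb flank by at least 1 bp was compared with 10000 random lists of the same size matched on gene-length decile. Adjustment was over the 23 lists. Background was all 27444 nuclear protein-coding genes, or all nuclear genes for microRNA genes. The genes named in the text were HDA6, genes with a symbol at the 25 widest regions, every list member with a region, and CCA1, LHY, TOC1, FLC, FT and SOC1. Genes at the 25 widest regions that have only a locus name are given as counts. Genes named in the other observations were chosen after their values were seen.

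Alternatives fixed before the data were examined changed the flank (500 bp and 2 kb), the distance from the centromere (2 and 4 Mb), the minimum overlap, the window around genes and the background of the placement, or kept the 3749 widest regions. Alternatives added after seeing the data placed regions within their own compartment or rotated all regions of a chromosome together. Others added then left out multi-copy loci or kept regions in narrow input intervals (no wider than 1130 bp). Multi-copy loci were the 25 widest nuclear regions and chromosome 2 from 3 to 3.6 Mb, in counts by gene also with the 313 genes there. For the annotation classes of the arms, the first 100 kb of chromosome 2 and chromosome 5 from 15660000 to 15700000 bp were left out too.

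The code was tested on simulated data. For 7477 placed regions, true excesses of 2.08-fold and 4.25-fold in annotated pseudogenes came back as 2.03-fold and 4.26-fold. Of 100 random region lists and of 200 random lists of 24 genes, 3% were called at 0.05, and of 200 lists of 24 genes with 40% of genes hit, 97.5% were called. These calls used an unadjusted p. In the real gene lists at most 21.05% of genes had a region, and the power to detect such shares was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.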

Results

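Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone deacetylase 6 (HDA6), an enzyme that removes acetyl groups from histones and is known for silencing repeats and transgenes. The plants were 14-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype carrying an HDA6 fusion to green fluorescent protein (HDA6-GFP) under the HDA6 promoter. The series holds 2 HDA6-GFP ChIP samples and 1 input sample. The deposited data analysed here are 1 list of ChIP regions and 1 list of input intervals, both on the TAIR10 build, with no value per region. Neither list separates the replicates, so none of the values below has a replicate error, and read depth is unknown. The question the design implies is where in the genome HDA6-GFP regions lie, relative to chance and to the input.

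HDA6-GFP ChIP regions were short and numerous. On the 5 nuclear chromosomes there were 7477 regions covering 3654788 bp, or 3.07% of the sequence, with a median width of 337 bp and a range of 141 to 137370 bp. Chromosomes 2 and 4 carried 81.3 and 88.4 regions per Mb, against 40.5 on chromosome 1, 59.3 on chromosome 3 and 59.7 on chromosome 5. A further 70 regions covered 91.4% of the mitochondrial genome, where input intervals covered 99.4%. The chloroplast genome held 0 ChIP regions, although 1 input interval spanned 100% of it. The input list had 169984 nuclear intervals with a median width of 464 bp that covered 97.8% of the nuclear sequence. All 7477 nuclear ChIP regions overlapped an input interval by at least 1 bp, but so did 99.9% of randomly placed regions, so overlap with the input could hardly separate ChIP regions from any other place (two-sided permutation p = 0.004 over 1000 random placements). Among the 3749 widest regions the same overlap did not pass the permutation test (adjusted p = 0.0779).

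HDA6-GFP regions were concentrated around the centromeres of all 5 chromosomes. Within 3 Mb of a centromere midpoint lay 5843 of the 7477 region midpoints, or 78.2% (95% Wilson interval 77.2 to 79.1%), against 26.4% of randomly placed regions, a 2.96-fold excess. The excess was 3.49-fold on chromosome 1, 2.66-fold on chromosome 2, 2.98-fold on chromosome 3, 2.59-fold on chromosome 4 and 3.53-fold on chromosome 5. The densest 500-kb bin, starting at 11.5 Mb on chromosome 5, held 353 regions. Of the input intervals, 27.2% lay within the same distance of a centromere, where 25.2% of the nuclear genome lies. As these intervals cover 97.8% of the nuclear sequence, their number there does not measure read depth. The highest of 1000 random placements put 28.3% of regions there (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Regions clustered along the chromosomes and were not independent of each other, so the placement p-values are too small. Rotating all regions of a chromosome together, which keeps the clusters, gave a central 95% range of 7.10 to 53.5% and a highest value of 75.03%, also below the observed share (permutation p = 0.002).

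**Figure D1:**
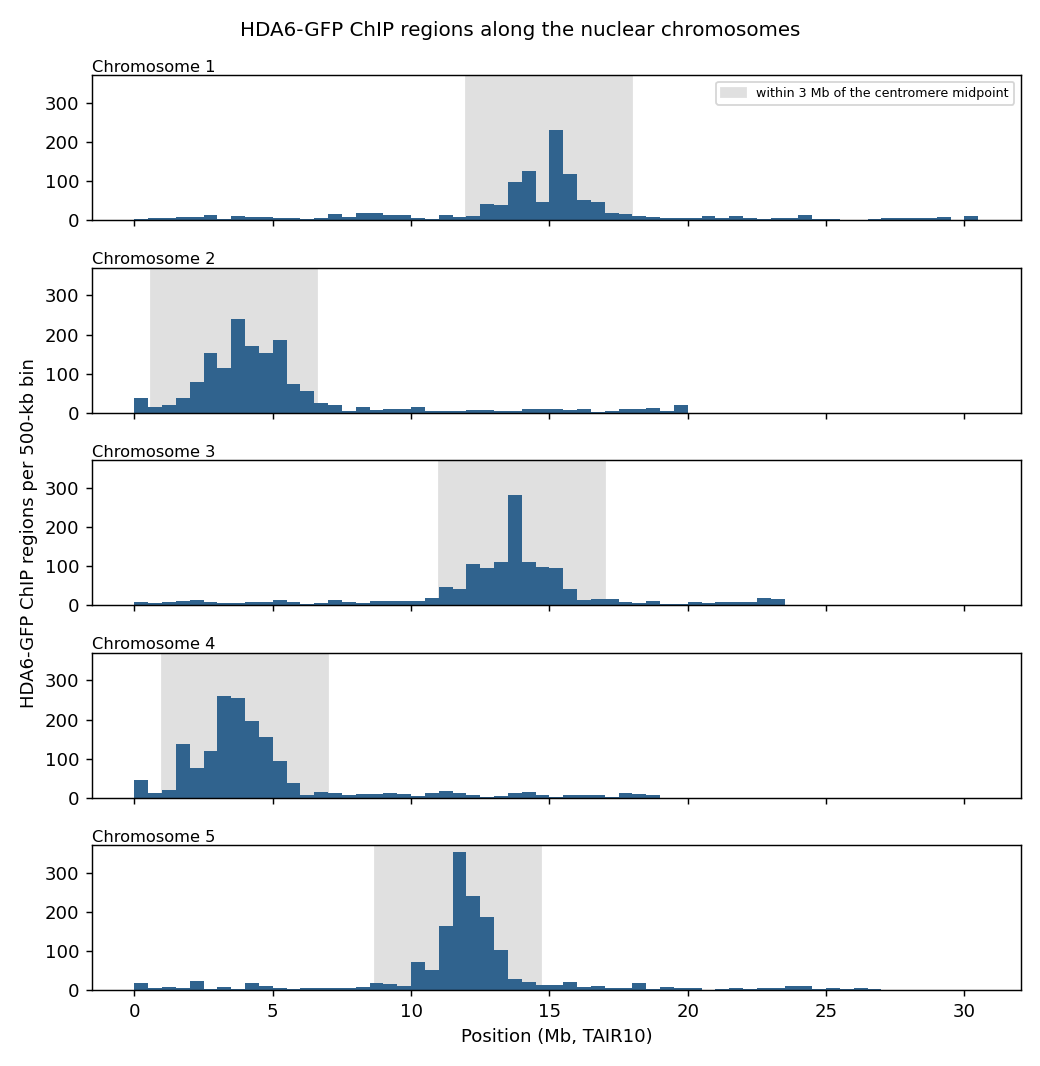
Number of HDA6-GFP ChIP regions (vertical axis) in each 500-kb bin along chromosomes 1 to 5 (horizontal axis, Mb on TAIR10), with the 3 Mb on either side of each centromere midpoint shaded. The tallest bar holds 353 regions, on chromosome 5, and the shaded parts hold 78.2% of all nuclear regions.

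Annotated pseudogenes, a class in which RefSeq commonly places transposon genes and which here pools genes annotated as pseudogenes and as transcribed pseudogenes, carried HDA6-GFP regions far more often than chance, and protein-coding genes and their flanks carried them less often. Midpoints lay in annotated pseudogenes for 42.9% of regions (95% Wilson interval 41.7 to 43.98%) against 8.43% of random placements, a 5.09-fold excess. Protein-coding gene bodies held 21.2% against 53.6%, the 1-kb flanks of those genes 4.75% against 20.4%, and other sequence 31.2% against 17.6%. The input list divided into 8.201% annotated pseudogenes, 48.2% gene bodies, 23.2% flanks and 20.5% other sequence. Since its intervals cover nearly all of the nuclear sequence, these shares do not measure read depth in any class. All 4 differences from random placement had a Benjamini-Hochberg adjusted p of 0.002 in a two-sided permutation test. Counted by gene within compartments, the transcribed pseudogenes of the pooled class had no excess (0.942-fold in the pericentromeres, 0.664-fold in the arms).

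Part of that contrast went with the position near the centromeres, and the chromosome arms had a different composition. When random placement kept each region in its own compartment, the excess in annotated pseudogenes was 2.01-fold, the deficit in gene bodies was 0.675-fold, and other sequence no longer differed from random placement by the test (0.997-fold, adjusted permutation p = 0.887). Inside the pericentromeres, 50.8% of 5843 midpoints lay in annotated pseudogenes against 26.9% of random positions there (1.89-fold), 7.02% in protein-coding gene bodies against 22.1%, and 3.63% in flanks against 14.1%. In the arms, gene bodies held 72.0% of 1634 midpoints, above the 64.8% of random positions (1.11-fold), whereas flanks held 8.75% against 22.6%. Annotated pseudogenes held 14.4% of arm midpoints against 1.80% (8.02-fold), and other sequence 4.77% against 10.8%. The comparisons within compartments were chosen after seeing the data. The 3 midpoint comparisons given for the pericentromeres had an adjusted permutation p of 0.00266 and the 4 given for the arms one of 0.002, and the same with regions rotated together. Counted by gene, 4.69% of arm protein-coding genes had a region in the body, against 4.96% under random placement (0.946-fold, adjusted permutation p = 0.00733). That count differs from the midpoint shares in 2 ways: it counts genes rather than regions, and it takes any overlap of the body. Random placement scattered clustered regions singly, and rotation was not run for counts by gene. The count therefore does not show that arm gene bodies held fewer regions than random positions.

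**Figure D2:**
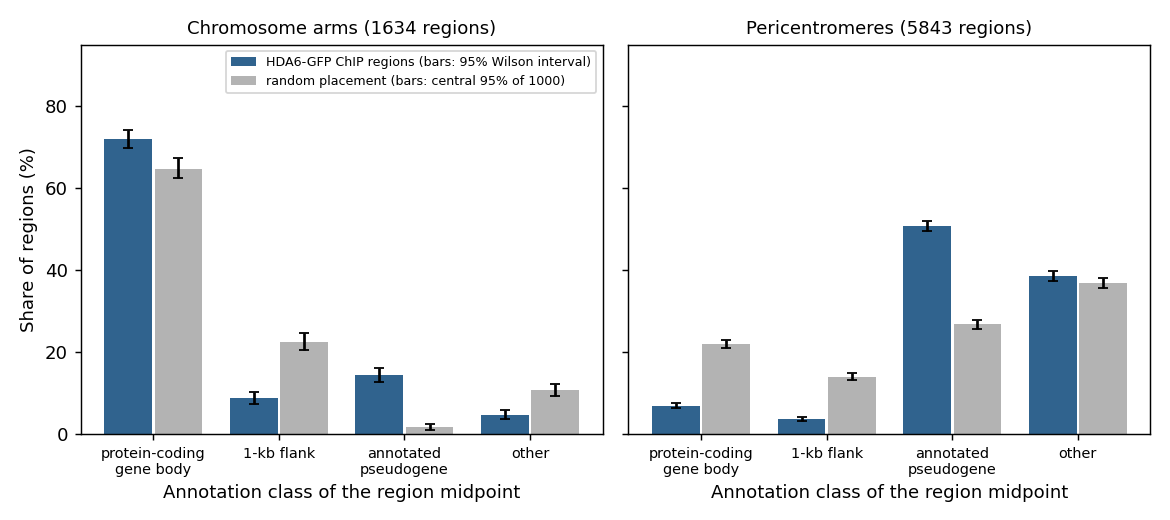
Share of region midpoints (vertical axis, %) in each annotation class (horizontal axis) for HDA6-GFP ChIP regions (blue, bars show 95% Wilson intervals) and random placements within the same compartment (grey, bars show the central 95% of 1000 placements). In the arms 72.0% of midpoints lay in protein-coding gene bodies, and in the pericentromeres 50.8% lay in annotated pseudogenes.

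Region midpoints lay near gene ends less often than random positions did. Within 1 kb of either end of a protein-coding gene lay 21.9% of midpoints (95% Wilson interval 21.01 to 22.9%) against 57.7% of random placements (0.380-fold, two-sided permutation p = 0.002). With placement kept within the compartment, the random share was 38.02% (0.577-fold). In the arms alone the shares were 65.7% and 67.7%, a difference that did not pass the permutation test (p = 0.102). The annotation used here gives no strand, so gene starts and gene ends were pooled.

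Counted by gene, 2348 of 27444 nuclear protein-coding genes (8.56%) had a region in the gene body or within 1 kb of it, and 1591 had one in the body. In the pericentromeres 641 of 3197 protein-coding genes (20.1%) had one, and in the arms 1707 of 24247 (7.04%). Against random placement within the compartment, protein-coding genes with a region in the body were fewer in both, at 14.2% against 37.2% in the pericentromeres (0.382-fold) and 4.69% against 4.96% in the arms (0.946-fold). Random placement scattered clustered regions singly, and rotation, which keeps clusters, was not run for any count by gene. The small difference in the arms therefore does not show that regions avoided these genes. Genes annotated as pseudogenes, without the transcribed ones, had a region in the body for 1715 of 3263 pericentromeric members (52.6% against 40.6%) and for 194 of 654 arm members (29.7% against 4.96%, 5.98-fold). Transcribed pseudogenes did not pass the test, with 104 of 415 pericentromeric members (25.1% against 26.6%, 0.942-fold, adjusted permutation p = 0.714) and 9 of 511 arm members (1.76% against 2.65%, 0.664-fold, adjusted permutation p = 0.453). Long non-coding RNA genes were below random in both compartments, with 41 of 573 pericentromeric genes (7.16% against 17.2%) and 25 of 2907 arm genes (0.860% against 1.67%). Non-coding RNA genes of the class ncRNA were below random in the pericentromeres, with 2 of 37 (0.214-fold, adjusted permutation p = 0.0165). Pericentromeric transfer RNA genes had an excess, with 25 of 62 (40.3% against 12.01%, 3.36-fold, adjusted permutation p = 0.0126), but 2 of 39 when multi-copy loci and the genes in them were left out. All 4 nuclear ribosomal RNA genes overlapped a region, and the 2 in the arms passed the test (31.8-fold, adjusted permutation p = 0.0342). Both of these lie in 1 region of 9658 bp, so the result rests on 1 locus, and 0 of 2 had a region without multi-copy loci. These tests by gene class were chosen after seeing the data, and the adjusted p over 22 combinations of class and compartment was 0.00733 in both compartments for protein-coding genes, pseudogenes other than transcribed ones and long non-coding RNA genes.

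The HDA6 gene (AT5G63110) lay in one of the widest regions of the chromosome arms. Its region on chromosome 5, 25315745 to 25320321, was 4577 bp wide, ranked 7 of 1634 arm regions, and also overlapped AT5G63120. The 6 wider arm regions lay in the first 100 kb of chromosome 2, at and beside ribosomal RNA genes, and in a cluster of germin genes on chromosome 5. The plants carry an HDA6 transgene, whose DNA maps to the same place. The input had 2 intervals over the region, covering 99.5% of it, and the wider measured 4493 bp. Random arm windows of the same width had a median widest input interval of 1969 bp and a 95th percentile of 3963 bp.

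**Figure D3:**
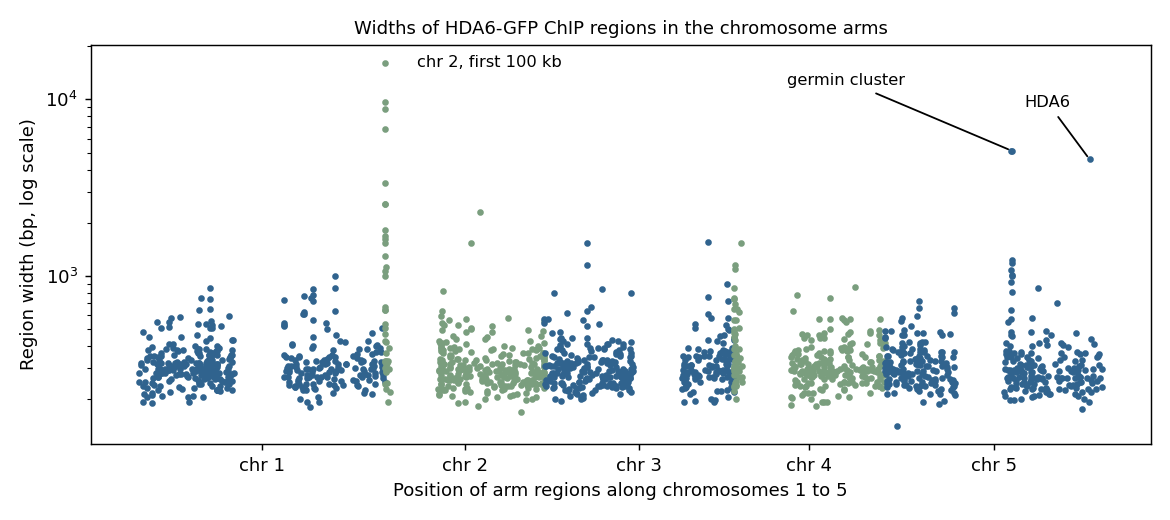
Width of each of the 1634 HDA6-GFP ChIP regions in the chromosome arms (vertical axis, bp, log scale) against its position along chromosomes 1 to 5 (horizontal axis, chromosomes end to end, pericentromeres left out). The 7 widest regions lie in the first 100 kb of chromosome 2, in the germin cluster and at HDA6, whose region is 4577 bp wide.

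The widest regions of the whole list lay in mitochondrial DNA, near centromeres and in the first 100 kb of chromosome 2, at and beside ribosomal RNA genes. Of the 25 widest, 7 were mitochondrial, 10 lay on chromosome 2, 1 on chromosome 3, 2 on chromosome 4 and 5 on chromosome 5. The widest of all ran from 3238952 to 3376321 on chromosome 2, where the reference holds a large insertion of mitochondrial DNA. Its 137370 bp overlapped 95 annotated genes, among them 49 protein-coding genes including ABCI5 (AT2G07771) and ABCI4 (AT2G07681), 24 annotated pseudogenes and 10 transfer RNA genes. On chromosome 2 from 3 to 3.6 Mb, 157 regions covered 55.7% of the sequence. Ribosomal RNA genes lay in the regions at 14191644 to 14206441 on chromosome 3, together with the microRNA gene MIR5642a, and at 988 to 10645 on chromosome 2, together with MIR5642b. The other microRNA genes among the 25 were MIR854b, MIR854d and MIR854e, in regions of 8281, 9240 and 11573 bp around the centromere of chromosome 5. Many of these loci hold sequence that is present in many copies. Of the 18 nuclear regions among the 25, 12 overlapped one of the 25 widest nuclear input intervals. In turn, all 25 widest nuclear input intervals held a ChIP region, and 89.0% of their bases lay in ChIP regions against 3.07% genome-wide.

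No list of named genes passed the test against random lists, and 8.56% of all protein-coding genes had a region under the same rule. Of the circadian clock genes, GI, which links the clock to flowering, and RVE8, a MYB-type clock activator, had a region (2 of 24). CCA1, LHY and TOC1, core clock transcription factors, had none. Of the flowering-time genes, FPA and LD, both of the autonomous pathway, had a region (2 of 26), whereas FLC, the floral repressor, and FT and SOC1, which promote flowering, had none. Among photosynthesis genes a region was found at LHCA1 and LHCA3, antenna proteins of photosystem I, PSAF, a photosystem I subunit, and PSBQ2, a photosystem II subunit (4 of 26). At LHCA3, PSAF and PSBQ2 the region lay in the flank, and with the gene body alone or a 500-bp flank the count was 1 of 26. The regions at RVE8, EXP7 and GAPC2 also lay in the flank. RD22, COR15B and RAB18, induced by drought or cold, had a region (3 of 24), as did EXP7, an expansin of root hairs, and PLT1, a root stem cell factor (2 of 12). Of the housekeeping genes EF1A3 and GAPC2 had a region (2 of 21). Light signalling genes (0 of 22) and jasmonate and ethylene genes (0 of 21) had none, but such short lists often have none by chance (permutation p = 0.278 and 0.328), so a deficit could not have passed.

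The seed maturation genes with a region were SESA1, SESA2, SESA3 and SESA4, which encode seed storage albumins (4 of 19). These 4 are neighbours on chromosome 4, with the widest region at each lying between 13607436 and 13614143, so they are not independent of each other. Among chromatin regulators, regions were found at HDA6, at HDA19, a related deacetylase (chromosome 4, 17896497 to 17896734), at LDL1, a histone demethylase (chromosome 1, 23266047 to 23266365), and beside DRM2, a DNA methyltransferase (chromosome 5, 4714378 to 4714571), or 4 of 27 genes. Outside HDA6, the widest region at any of the named list members measured 566 bp, at SESA3. The GI region lay at 8063624 to 8063884 on chromosome 1, that of FPA at 18028066 to 18028347 on chromosome 2, and that of PLT1 at 7302641 to 7302976 on chromosome 3.

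Families defined by their symbols did not pass the test either. A region was found for 22 of 229 cytochrome P450 genes (17.2 in random lists), 29 of 326 microRNA genes (25.4), 8 of 120 MYB factors (9.58), 5 of 67 WRKY factors (5.30), 5 of 81 NAC factors (6.54), 3 of 34 ERF and DREB factors (3.005), 3 of 24 Aux/IAA genes (1.97), 2 of 44 cytosolic ribosomal protein genes (3.67), 1 of 25 BBX factors (1.98), 1 of 16 SAUR genes (1.65) and 1 of 19 heat shock protein genes (1.65). TCP factors (0 of 16) and response regulators (0 of 7) had none. Over the 23 lists, 0 passed at an adjusted p of 0.05 in the two-sided permutation test against 10000 random lists matched on gene length, and 0 had an unadjusted p under 0.05. The smallest unadjusted p was 0.158, for seed maturation. Fisher's exact test, without matching on length, gave 1 list at an unadjusted p under 0.05, the microRNA genes, with 29 genes against the 44.9 it expected (p = 0.00955), and 0 after adjustment.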

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

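The tests within compartments, with rotated regions, without multi-copy loci, in narrow input intervals and by gene class were chosen after the results were seen; the others were fixed before. The pericentromeric excess stayed between 2.37-fold (within 4 Mb) and 3.98-fold (within 2 Mb). The excess in annotated pseudogenes kept its direction and passed under each alternative run, from 1.89-fold in the pericentromeres to 8.02-fold in the arms, and so did the deficit in flanks. Gene bodies were reversed in the arms, at 1.11-fold, at 1.12-fold without multi-copy loci and at 1.11-fold with rotation. For these shares of the arms, the loci left out included the first 100 kb of chromosome 2 and the germin cluster of chromosome 5. Other sequence was reversed in the arms (0.443-fold, 0.436-fold without multi-copy loci, 0.445-fold with rotation). When placement kept the compartment it no longer differed from random placement by the test (0.997-fold, adjusted permutation p = 0.887). With rotation within the pericentromeres it was 1.046-fold and no longer passed (adjusted permutation p = 0.513). Distance to gene ends was 0.577-fold with placement within the compartment and no longer passed in the arms, at 0.971-fold and at 0.972-fold with rotation. Overlap with the input among the 3749 widest regions was 1.001-fold of random and did not pass, with fewer regions. Leaving out multi-copy loci lowers counts by gene by construction, since those loci were chosen for wide ChIP regions. Pericentromeric transfer RNA genes turned from a 3.36-fold excess to 0.348-fold without the loci, or 0.551-fold (adjusted permutation p = 0.782) when their genes were left out as well. With both left out, values below random passed for pericentromeric transcribed pseudogenes (from 0.942-fold to 0.785-fold) and genes of the class misc_RNA (from 0.758-fold to 0.116-fold), which shows no deficit of these classes as a whole. Ribosomal RNA genes in the arms went to 0-fold for the same reason. For the other changes the cause was not tested. Of the gene lists, 0 passed after adjustment under any alternative; at an unadjusted p under 0.05 there were 2 with the gene body alone (the smallest p being 0.0156, for cytochrome P450) and 1 with Fisher's exact test. No ChIP region lay outside the input intervals, so leaving out shared regions gave no value. Motif and base composition alternatives were not run. No paired analysis was possible because the lists carry no replicate, and leaving out a replicate was not possible for the same reason.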

Other observations

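Several regions of the chromosome arms fell in genes for proline-rich cell wall proteins; these genes and the tests of symbol stems were chosen after their values were seen. EPR1 (AT2G27380), an extensin-type gene, had a region of 2296 bp on chromosome 2, 11713433 to 11715728, and EXT6 (AT2G24980), an extensin, one of 1541 bp at 10622560 to 10624100. Of 218 symbol stems with at least 8 arm genes, 3 had more genes with a region in the body than expected by a one-sided Fisher's exact test, adjusted over the 218. This test did not match on gene length, and proline-rich cell wall genes were not tested as a group. PRP had 5 of 8 (0.407 expected, adjusted exact p = 0.00357): PRP1 to PRP4, which encode proline-rich cell wall proteins, and PRP39, which shares only the letters. GRP had 5 of 13 (adjusted exact p = 0.0331), a stem that mixes glycine-rich proteins with others. LSH had 4 of 9 (adjusted exact p = 0.0491): LSH2, LSH4, LSH5 and LSH10. Extensins and proline-rich proteins are known for short repeated motifs, and the mapping of reads from such repeats was not tested.

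Among the 25 widest nuclear input intervals, 2 on chromosome 1 had little ChIP coverage, 19.02% at 8784222 to 8794942 and 4.24% at 8802334 to 8812807. Arm regions in annotated pseudogenes lay in input intervals with a median width of 1397 bp, 1.22 times that at random positions of the same class. The ratio was above 1 in all 1000 draws. Whether a read excess that the input shares gave part of the 8.02-fold excess of this class in the arms was not tested.

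In the weighing that follows, the test against windows of equal width at HDA6 was chosen after the result was seen, and the other tests were set out before their values were seen but after the patterns were. The multi-copy loci left out held only 174 of the 7477 regions, too few to account for the concentration around the centromeres, which was 2.95-fold without them. A read excess confined to input intervals wider than 1130 bp was argued against as the whole cause. The concentration was 2.82-fold among the 3421 regions in input intervals no wider than that. That limit is the median width taken over covered nuclear positions. The median over intervals was 464 bp, so most input intervals fall under the limit. An excess that does not widen intervals past the limit would escape this test. Part of the concentration may still come from an excess that the input shares, but interval width could not show this. Input intervals at pericentromeric regions were 1.13 times as wide as at random covered positions of the pericentromeres. For arm regions the ratio to random arm positions was 1.076. Both ratios compare positions within 1 compartment, so they do not bear on why regions concentrate around the centromeres. The median input interval width at random covered positions was 1059 bp in the pericentromeres and 1154 bp in the arms. HDA6-GFP occupancy of transposon-rich chromatin is a candidate explanation too. Annotated pseudogenes were 1.89-fold over random positions of the pericentromeres, although the annotation does not mark which of them are transposons. That excess comes from the same regions as the concentration. The mapping of reads from repeats could give it as well, so it does not favour occupancy. Interval width is an indirect measure of depth, and the mapping of reads from other repeats was not tested. An excess that the input shares and HDA6-GFP occupancy therefore both stay open. The series holds no ChIP of plants without the GFP fusion, so nuclear regions that do not depend on HDA6-GFP could not be told apart. The list itself holds 70 regions in mitochondrial DNA, covering 91.4% of that genome. Its widest nuclear region lies at the insertion of mitochondrial DNA on chromosome 2. What gave these regions was not tested, and similar background elsewhere in the nucleus stays possible.

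The wide region at HDA6 is a single locus in plants that carry an HDA6 transgene. The widest input interval there was at percentile 98.6 of random arm positions, a comparison that favours a wide region, and at percentile 97.2 of random arm windows of the same width. Extra transgene copies of HDA6 DNA, present in the input as well, may therefore account for part of it. Binding of HDA6-GFP to its own gene was not tested and stays open.

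Arm region midpoints lay in gene bodies more often (1.11-fold) and in flanks less often than random positions did. Counted by gene, the protein-coding genes of the arms with a region in the body were at 0.946-fold of random placement. That count takes any overlap and was not run with rotation, so it cannot be set against the midpoint shares. A read excess that the input shares was tested on the regions in gene bodies, whose input intervals were 0.992 times as wide as at random arm gene-body positions, with 620 of 1000 draws at or below 1. That number falls between the limits set beforehand, so an excess in the input and an occupancy of gene bodies cannot be told apart by interval width.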
